A study of Mus musculus with 12 samples.

How the data were processed

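RNA sequencing libraries were made from 12 mRNA samples of C57BL/6 mouse cells in 3 groups of 4: primary cultured normal endometrial cells (called normal below) and the endometrial cancer cell lines mECC and HPmECC. The series' design text says that Myc was overexpressed in some of the cancer lines, and the labels do not say in which. Sample titles also carry the codes B6 for normal, DM for mECC and WT for HPmECC, which the titles do not explain. No library was grouped by its Myc level. Total RNA was purified with RNeasy kits and libraries were prepared with a TruSeq mRNA kit, per the labels' protocols.

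The submitters' processing notes name Trim Galore for trimming, STAR 2.6.1a for alignment, RSEM 1.3.1 for quantification and mouse genome build GRCm38. The annotation release, the strand setting and the version of Trim Galore are not given in the sources used here. The deposited estimated counts are RSEM expected counts per gene, and they were rounded to whole numbers before any count test. The deposited TPM values, which the authors scaled to transcript length and to a fixed sum per library, served only for alternatives and for a check of transcript length. FPKM values were not used here. RSEM divides reads that fit several genes or transcripts in proportion to their estimated abundance, so values of near-identical relatives, such as the H2 class I genes, are uncertain. Because no strand setting is stated, genes that overlap on opposite strands, such as Xist with Tsix, are uncertain as well. Sox2, which lies inside Sox2ot, is uncertain because the genes overlap.

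The count table held 55385 gene identifiers, of which 55144 matched a symbol in the gene name table used here. Coordinates came from the GENCODE mouse annotation of release 21 on GRCm38, which held 15276 of the 15283 genes tested. The libraries had 16332060 to 26873582 counts in total. At this depth the biological coefficient of variation over all libraries was 4.27%. Counting intervals and floors cover counting error only, because amplified reads carry no molecular identifiers. A group with 0 counts of a gene was set to a floor of 3 counts over its 4 libraries, and the fold was then given as a lower bound. With 1 to 3 counts, the ratio was given with its exact 95% counting interval.

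Differences were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test over all 12 libraries with 1 coefficient per group, TMM factors, and the filterByExpr filter at its default minimum of 10 counts. Adjusted p-values are Benjamini-Hochberg values over the 15283 genes, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values are TMM-scaled, and errors after ± are SD over 4 libraries unless marked SE. Of 25 gene lists, 24 had at least 5 tested genes. They were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and again with a correlation estimated from the data. Camera p-values were adjusted over the lists within each comparison. The fry test was run beside them. It asks whether a list's genes move on balance in a given direction, without comparing them with other genes.

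The gene lists, tests and alternatives were chosen before the data were examined, apart from a block named below and the tests that the closing parts name as later choices. So was the rule for the genes named. For each comparison it took Myc and Ccl7, and the 4 genes with the highest and the 4 with the lowest fold change. These needed at least 10 CPM in the higher group, no overlap between the groups' libraries, and a name other than that of a predicted gene model. It also took up to 2 called members of each list with the largest change and at least 5 CPM in the higher group, and up to 4 for myeloid chemokines. For the comparisons with normal cells, only lists called by camera and cell type marker lists were used. The rule gave 57 genes for HPmECC against mECC and 35 for each comparison with normal cells; some of them are not reported here. Other genes are named because they belong to a list described, or because their values stood out; they were chosen after the values were seen. These are Trp53, Cdkn2a, Epcam, Cdh1, Xist, Vim, Col1a2, Col3a1, Col6a1, Pgr, Esr1, Pax8, Ccl2, Ccl5, Csf3, H2-K1, H2-D1, Ldha, Ncl, Npm1, Mycn, Krt7, Krt8, Krt19, Prdm6, Wnt4, Slc2a1, Peg3, H19, Igf2 and Pvt1. So were Snai1, Cxcl12, Fgfr2, Sox2, Foxd1, Sox17, Prap1, Ltf, Flt1, Egfl7, Bnc1 and Acta2 in the comparisons for which the rule had not picked them.

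The alternatives were median-of-ratios factors, library totals without TMM, no filter on low counts, and a minimum of 10 CPM in 4 libraries. Further ones were DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1), a fit of only the 2 groups compared, the replicate number as a block, a minimum log2 fold change of 1, and each library left out in turn. A block of replicates 1 and 2 against 3 and 4 was added after seeing the data. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

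The procedure was tested on simulated counts for the 15283 genes, in which 50 genes were changed at each of 4 fold sizes. For HPmECC against mECC, edgeR recovered 54% of genes changed 1.2-fold, 84% at 1.5-fold, 96% at 2-fold and 100% at 4-fold. It called 11 unchanged genes. In a simulated comparison of the same groups, camera called the raised list and 0 of 24 unchanged lists. The simulated genes varied independently and the lists were random, so the preset correlation was not tested on related genes. Few genes were changed in the simulations, so the scaling was not tested for groups that differ in most genes. Within each group, the counts of every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom from 2.58 to 7.09. Each library was counted as 1 replicate, but this spread may be technical and does not show that the libraries came from separate cultures.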

Results

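Gene expression was measured in cultured normal mouse endometrial cells and in the endometrial cancer lines mECC and HPmECC, with 4 libraries in each group. Library totals ran from 16332060 to 24202564 counts in the normal group, from 21755275 to 25821106 in mECC and from 18402202 to 26873582 in HPmECC. The first principal component held 82.6% of the variance and set normal cells apart from both cancer lines, and the second held 13.1% and set HPmECC apart from mECC. Mitochondrially encoded transcripts made up 1.04% ± 0.23 of counts in normal cells, 1.29% ± 0.12 in mECC and 1.37% ± 0.07 in HPmECC. The labels do not say that the 4 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical.

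**Figure D1:**
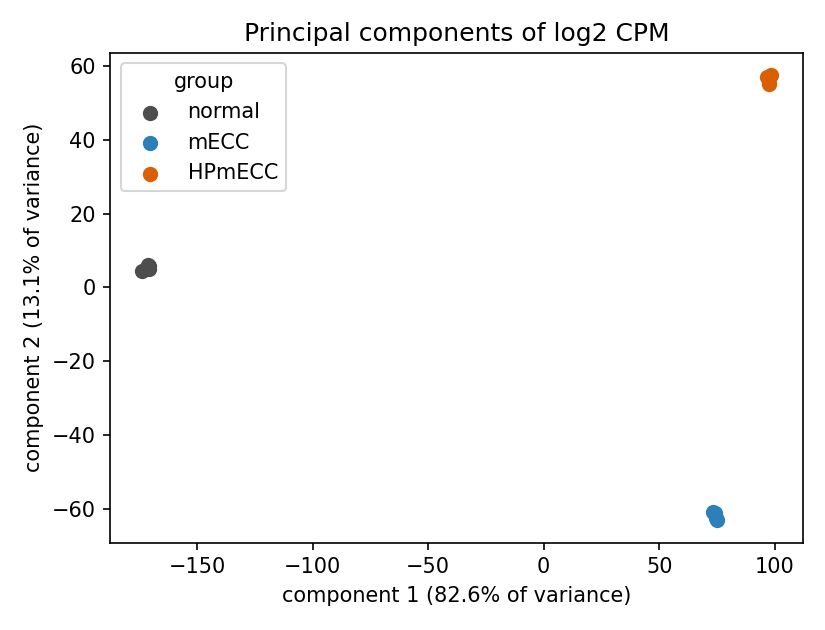
Principal components of log2 CPM over the 15283 genes tested, with each point a library and each color a group of 4. Component 1 (82.6% of variance) separates the normal libraries from both cancer lines, and component 2 (13.1%) separates HPmECC from mECC.

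Myc, the transcription factor that the series' design text says was overexpressed in some of the cancer lines, was highest in HPmECC. The labels do not say in which line it was overexpressed. Its gene (ENSMUSG00000022346) lies on chromosome 15 at 61985391 to 61990374 of GRCm38. It stood at 266 ± 24 CPM in HPmECC, 59.4 ± 2.09 CPM in mECC and 111 ± 5.05 CPM in normal cells (SD, n = 4 each). The 4 HPmECC libraries held 257, 248, 258 and 302 CPM, and none of the other 8 libraries exceeded 117 CPM. HPmECC was 4.48-fold above mECC (log2 fold change 2.165, SE 0.05, edgeR adjusted p = 9.14e-17) and 2.40-fold above normal cells (1.26, SE 0.05, edgeR adjusted p = 1.92e-14). mECC lay 1.87-fold below normal cells (log2 fold change -0.90, SE 0.06, edgeR adjusted p = 1.16e-11). From TPM, which also depends on transcript length, the log2 fold change between the lines was 2.53, and the Myc transcripts implied by counts over TPM were 25.8% shorter in HPmECC than in mECC. Ccl7, a chemokine that attracts monocytes (ENSMUSG00000035373, chromosome 11 at 82045712 to 82047525), ordered the groups the same way, at 28.4 ± 3.44, 9.53 ± 0.79 and 20.3 ± 1.08 CPM in HPmECC, mECC and normal cells. It was 2.97-fold higher in HPmECC than in mECC (log2 fold change 1.57, SE 0.08, edgeR adjusted p = 5.13e-12).

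**Figure D2:**
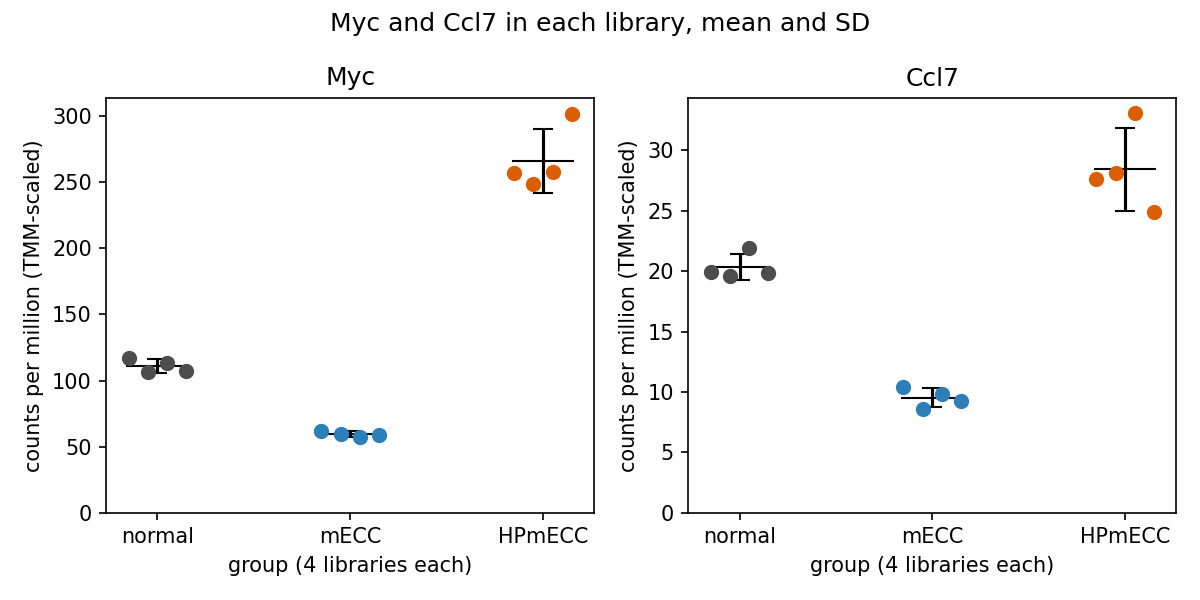
TMM-scaled CPM of Myc and Ccl7 in each of the 12 libraries, with each point a library and black bars the mean and SD of 4. Both genes were highest in HPmECC and lowest in mECC, and for Myc the lowest HPmECC library (248 CPM) was above the highest normal library (117 CPM).

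The comparison of HPmECC with mECC asks how the cancer lines differ from each other. All 28 tested epithelial genes were lower in HPmECC, although the keratin genes Krt8 (124 against 208 CPM) and Krt19 (96.4 against 330 CPM) kept transcripts. Most genes of ribosome assembly, DNA replication, mitosis, glycolysis and cholesterol synthesis were higher; as lists these were called by camera, and with an estimated correlation none of the 5 was (adjusted p from 0.118 to 0.404). The adhesion gene Cdh1 (E-cadherin) stood at 0.94 ± 0.25 CPM in HPmECC and 105 ± 2.51 CPM in mECC, and the epithelial surface gene Epcam at 0.34 ± 0.16 and 92.6 ± 2.93 CPM (SD, n = 4). Snai1, a repressor of Cdh1, was 4.51-fold higher in HPmECC, at 72.9 ± 1.97 against 16.2 ± 0.77 CPM (log2 fold change 2.17, SE 0.04, edgeR adjusted p = 7.13e-18). In total, 5165 genes were higher and 5275 lower in HPmECC out of 15283 tested, which is 68.3% of them. With a change of at least 2-fold required as well, 1029 were higher and 1436 lower.

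The largest rises among well-expressed named genes were in Cspg4, a cell surface proteoglycan (162-fold, from 0.237 ± 0.217 to 40.6 ± 3.93 CPM), and Klhl30 (65.3-fold, from 0.864 ± 0.105 to 56.8 ± 2.21 CPM). Acan, which encodes the cartilage proteoglycan aggrecan, rose 48.0-fold and Hspb7, a small heat shock protein gene, 35.8-fold. At the other end, Cdh16, a cadherin of kidney and other epithelia, had 33.6 ± 3.02 CPM in mECC and 0 counts in HPmECC, at least 1090-fold lower. Ppp2r2c, a phosphatase subunit gene, had 1 count in HPmECC against 2795 in mECC (95% counting interval of the ratio 480 to 106000, for counting error only). Esrp1, an epithelial splicing regulator, fell 377-fold. The highest edgeR adjusted p among these 7 genes was 4.79e-15.

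All 28 tested epithelial genes were lower in HPmECC, 25 of them at least 2-fold, with a median log2 fold change of -4.12. The list was called by camera (adjusted p = 1.25e-13) and the call held with an estimated correlation (adjusted p = 0.0395). Ap1m2, a subunit of an epithelial sorting complex, had 1 count in HPmECC and 612 in mECC (counting interval of the ratio 105 to 23200), and the keratin gene Krt7 went from 604 ± 3.11 to 30.8 ± 1.06 CPM. The mesenchymal and fibroblast list did not move as a set, with 15 of 29 genes higher, 13 lower and camera adjusted p = 0.696. Within it Mmp2, a matrix protease gene, was 7.54-fold higher in HPmECC (260 ± 6.31 against 34.6 ± 1.33 CPM), and Vim, already abundant in mECC at 2071 ± 45.3 CPM, stood at 2386 ± 44.9 CPM. Smooth muscle genes were higher, 9 of 12 with 0 lower, led by Des (6.76-fold) and Acta2 (4.33-fold). Their camera call (adjusted p = 0.00399) was lost with an estimated correlation (adjusted p = 0.305).

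Uterine identity and hormone response genes were mostly lower in HPmECC, 19 of 28 with 5 higher (camera adjusted p = 0.0015; adjusted p = 0.0395 with an estimated correlation). Wnt7a, a signaling gene of the uterine epithelium, fell 168-fold to 5 counts over the 4 libraries, and Foxj1, a regulator of ciliated cells, fell 42.6-fold from 25.1 ± 1.89 to 0.58 ± 0.17 CPM. Pax8, a lineage factor of Müllerian epithelium, went from 31.9 ± 1.40 to 1.75 ± 0.26 CPM, and Wnt4 from 55.8 ± 0.97 to 3.41 ± 0.72 CPM. The progesterone receptor gene Pgr remained at 59.2 ± 7.55 CPM in HPmECC against 83.8 ± 7.10 CPM, and the estrogen receptor gene Esr1 at 39.3 ± 3.02 against 55.9 ± 2.77 CPM.

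**Figure D3:**
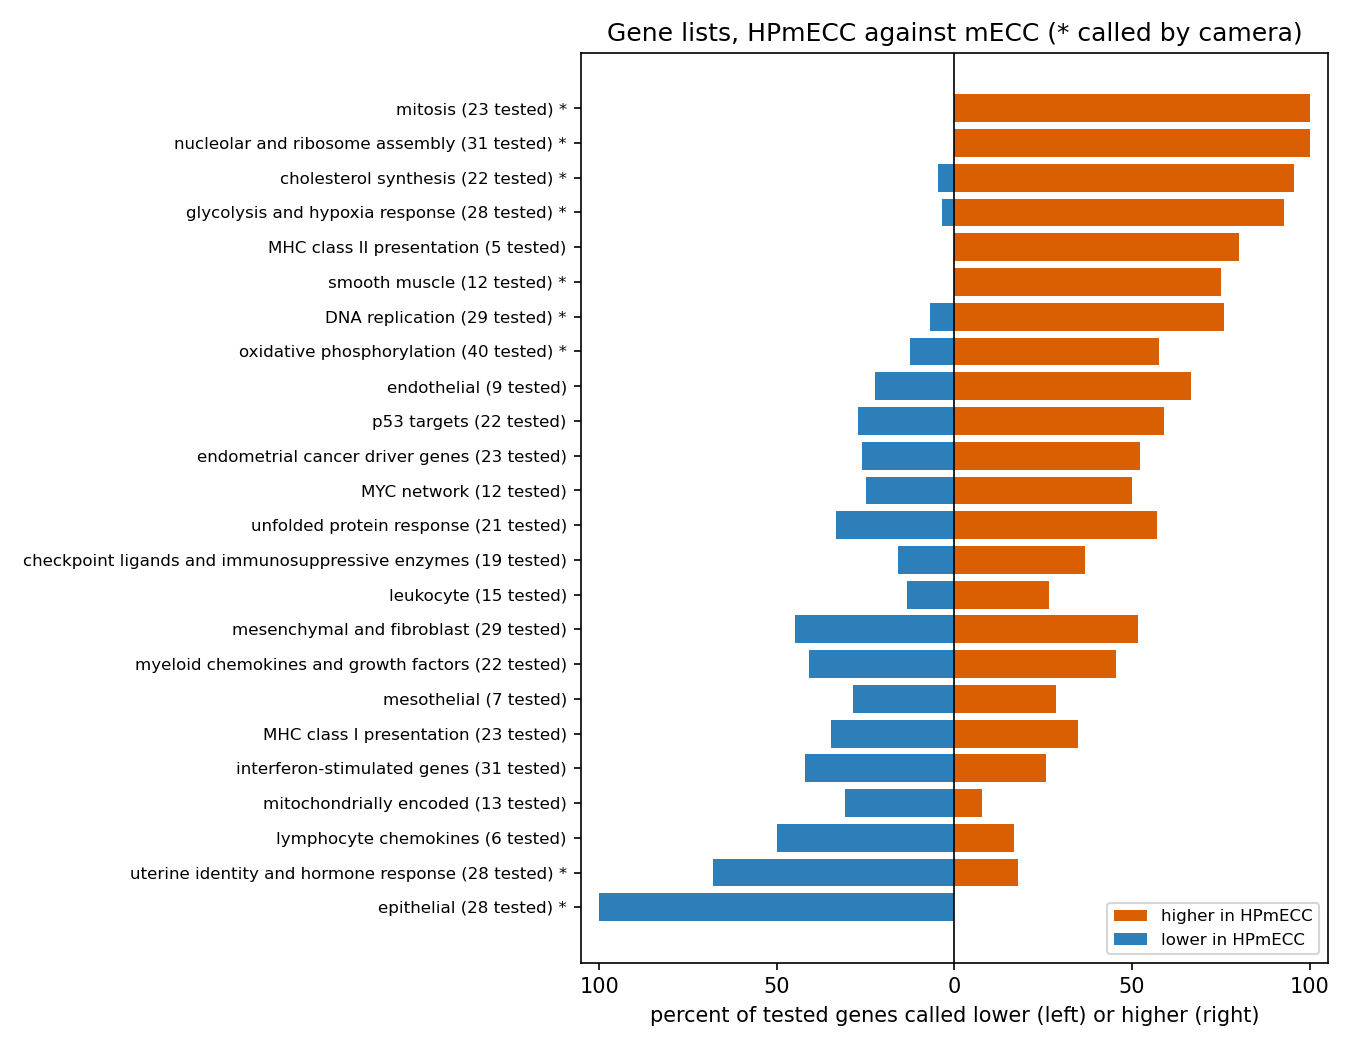
Percent of the tested genes of each of 24 gene lists called higher (right) or lower (left) in HPmECC than in mECC at an edgeR adjusted p under 0.05, with an asterisk where camera called the list. All 28 epithelial genes were lower, and all 31 nucleolar and all 23 mitosis genes were higher.

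Genes of nucleolar and ribosome assembly, many of them known targets of Myc, were all higher in HPmECC, 31 of 31, by small amounts: the median log2 fold change was 0.38 and 0 genes reached 2-fold. With library totals in place of TMM 28 of the 31 were called higher and 0 lower. Examples were Rrp9 (1.72-fold) and Dkc1 (1.67-fold). The camera call (adjusted p = 1.33e-10) was lost with an estimated correlation (adjusted p = 0.118). All 23 mitosis genes were also higher, with Cenpf at 1.73-fold and Cdc20 at 1.66-fold (camera adjusted p = 1.11e-09; adjusted p = 0.223 with an estimated correlation). Of 29 DNA replication genes, 22 were higher and 2 lower, with Mcm6 at 1.72-fold and Cdt1 at 1.71-fold (camera adjusted p = 3.76e-04; adjusted p = 0.404 with an estimated correlation). Among 12 genes of the MYC network itself, 6 were higher and 3 lower (camera adjusted p = 0.486). Mxi1, which encodes an antagonist of Myc, was 1.65-fold higher, and Mycn fell from 112 counts in mECC to 2 counts.

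Metabolic genes were mostly higher as well. In the glycolysis and hypoxia list 26 of 28 genes were higher and 1 lower, among them Car9 (9.04-fold, carbonic anhydrase), Egln3 (5.62-fold, an oxygen-sensing hydroxylase) and Ldha (1.87-fold, 1676 ± 216 against 895 ± 50.4 CPM). Camera gave adjusted p = 7.22e-08, and adjusted p = 0.305 with an estimated correlation. HPmECC replicate 4 stood apart in this group, with Car9 at 8.25 CPM against 3.68 to 4.26 CPM in the other 3 and Egln3 at 52.5 CPM against 28.2 to 36.0 CPM. Without it the log2 fold change of Car9 was 2.83 in place of 3.18 and that of Egln3 2.27 in place of 2.49, and the camera adjusted p was 4.00e-10. In cholesterol synthesis 21 of 22 genes were higher and 1 lower, with Pmvk at 2.15-fold and Idi1 at 2.07-fold (camera adjusted p = 5.28e-10; adjusted p = 0.118 with an estimated correlation). Of 40 oxidative phosphorylation genes, 23 were higher and 5 lower, with a median log2 fold change of 0.13 (camera adjusted p = 0.00763; adjusted p = 0.315 with an estimated correlation). Cyc1 was 1.41-fold and Uqcrc2 1.33-fold higher. Mitochondrially encoded genes were not called (1 of 13 higher, 4 lower, camera adjusted p = 0.60), and mt-Co1 and mt-Cytb moved in opposite directions, by 1.39-fold and 1.46-fold.

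Immune genes split in both directions, and none of these lists was called by camera. Of 22 myeloid chemokines and growth factors, 10 were higher and 9 lower in HPmECC (camera adjusted p = 0.696). Beside Ccl7, Mif was 1.97-fold higher and Ccl2 stood at 31.2 ± 2.76 against 16.3 ± 0.88 CPM. Cxcl12, which attracts lymphocytes and stem cells, was 2.14-fold lower but remained abundant at 965 ± 41.5 CPM, and Cxcl5, a neutrophil chemokine, was 2.21-fold lower. Csf3, the granulocyte growth factor gene, had 106 counts in mECC and 0 in HPmECC. Of 6 lymphocyte chemokines, 1 rose (Cxcl10, 4.98-fold) and 3 fell, led by Cxcl16 (3.94-fold; camera adjusted p = 0.696). Ccl5 stood at 4.59 ± 0.42 CPM in HPmECC and 0.27 ± 0.13 CPM in mECC. Of 31 interferon-stimulated genes, 8 were higher and 13 lower (camera adjusted p = 0.638), with Ifit1 3.78-fold higher and Irgm1 2.90-fold lower.

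Antigen presentation genes of MHC class I also divided, 8 of 23 higher and 8 lower (camera adjusted p = 0.897). The classical H2-K1 and H2-D1 were 2.11-fold and 1.97-fold higher in HPmECC, whereas H2-T23 was 3.94-fold and the peptide editor gene Tapbpl 2.19-fold lower. Of 5 MHC class II genes, 4 were higher and 0 lower. Cd74, the class II chaperone, went from 1.296 ± 0.143 to 12.5 ± 0.62 CPM, and H2-DMb1 from 3.78 ± 0.55 to 17.4 ± 1.17 CPM. The list missed the camera threshold (adjusted p = 0.0621), and passed it without HPmECC replicate 1 (camera adjusted p = 0.0412) and with library totals (camera adjusted p = 0.0399). Of 19 checkpoint ligands and immunosuppressive enzymes, 7 were higher and 3 lower (camera adjusted p = 0.273). Nt5e, which encodes the adenosine-producing enzyme CD73, was 5.48-fold higher, and Arg1, which encodes arginase, 5.02-fold higher.

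Other lists were not called between the lines. Of 22 p53 targets 13 were higher and 6 lower (camera adjusted p = 0.148), with Cdkn1a 2.03-fold higher and Pmaip1 2.04-fold lower. Of 23 endometrial cancer driver genes 12 were higher and 6 lower (camera adjusted p = 0.203), with Fgfr2 6.19-fold higher and Erbb3 10.2-fold lower. Unfolded protein response genes numbered 12 higher and 7 lower of 21 (camera adjusted p = 0.193), led by Trib3 (4.96-fold) and Chac1 (3.58-fold). Endothelial genes numbered 6 higher and 2 lower of 9 (camera adjusted p = 0.154), with Flt1 7.78-fold and Egfl7 2.93-fold higher. Leukocyte genes numbered 4 higher and 2 lower of 15 (camera adjusted p = 0.638), with Cd68 1.62-fold higher and Cd14 3.79-fold lower. Mesothelial genes numbered 2 higher and 2 lower of 7 (camera adjusted p = 0.696), with Bnc1 2.52-fold higher and Msln 3.98-fold lower. Each gene given with a fold change for these 6 lists passed the edgeR threshold, with adjusted p-values of at most 6.44e-06. The median and the mean of the log2 fold changes differed in sign for the MYC network (0.09 and -0.15), interferon-stimulated genes (-0.12 and 0.33) and checkpoint ligands (-0.04 and 0.25). For myeloid chemokines both were negative (-0.14 and -0.38) while camera's direction was up. Under library totals the median of MHC class I genes turned from 0.03 to -0.02. Counts adjusted over the list alone were equal to these except in DNA replication (22 higher, 4 lower), p53 targets (14 higher, 6 lower), MHC class I (9 higher, 8 lower) and mitochondrially encoded genes (1 higher, 2 lower).

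The comparison of mECC with normal cells asks how this cancer line differs from cultured endometrium. Transcripts of the tumor suppressor gene Trp53 (p53) were 65.9-fold lower in mECC, and most genes that p53 is known to activate were lower too. Trp53 (ENSMUSG00000059552, chromosome 11 at 69580359 to 69591873) stood at 2.14 ± 0.095 CPM in mECC and 141 ± 5.91 CPM in normal cells (SD, n = 4; log2 fold change -6.04). Of 22 p53 targets 19 were lower and 3 higher. Cdkn1a, the cell cycle inhibitor p21, was 19.6-fold lower (20.5 ± 1.10 against 402 ± 8.79 CPM) and the receptor gene Eda2r 368-fold lower. The camera call (adjusted p = 1.56e-04) held with an estimated correlation (adjusted p = 0.0269). Cdkn2a (chromosome 4 at 89274471 to 89294653), which encodes inhibitors of the cell cycle, stood at 154 ± 3.30 against 1.03 ± 0.32 CPM.

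In all, 6436 genes were higher and 6748 lower in mECC than in normal cells, 86.3% of those tested, and with a 2-fold minimum 2805 and 3485. The normal cultures held epithelial transcripts together with markers of leukocytes, smooth muscle, endothelium and mesothelium, and most genes of each of these lists were lower in mECC. Of 28 epithelial genes 26 were lower and 1 higher, with Ovol1 130-fold and Muc1 63.0-fold lower (camera adjusted p = 1.28e-09; adjusted p = 0.105 with an estimated correlation). Cdh1 nevertheless remained at 105 ± 2.51 CPM, against 838 ± 23.9 CPM in normal cells. All 15 leukocyte genes were lower, with Lyz2, a lysozyme gene of myeloid cells, at 96.7 ± 6.61 CPM in normal cells and 7 counts in mECC, and Laptm5 1470-fold lower (camera adjusted p = 5.56e-04; adjusted p = 0.0966 with an estimated correlation). Of 12 smooth muscle genes 11 were lower and 1 higher, with Tagln at 1267 ± 111 against 1.12 ± 0.32 CPM and Cnn1 150-fold lower (camera adjusted p = 0.00106; adjusted p = 0.296 with an estimated correlation). Endothelial genes were lower in 8 of 9 cases, with Cdh5 893-fold and Esam 132-fold lower (camera adjusted p = 0.0115; adjusted p = 0.296 with an estimated correlation). All 7 mesothelial genes were lower (camera adjusted p = 0.00534; adjusted p = 0.296 with an estimated correlation), and Wt1 had 28.4 ± 3.42 CPM in normal cells and 0 counts in mECC, at least 965-fold lower. Upk1b also had 0 counts in mECC, at least 575-fold lower.

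Mesenchymal and fibroblast genes were mostly higher in mECC, 21 of 29 with 7 lower (camera adjusted p = 6.05e-04; adjusted p = 0.408 with an estimated correlation). Postn, the matrix protein periostin, stood at 931 ± 40.1 against 1.61 ± 0.39 CPM, and the collagen genes Col3a1 and Col6a1 reached 2531 ± 112 and 3414 ± 170 CPM against 119 ± 11.1 and 43.3 ± 3.20 CPM. Thy1, a fibroblast surface gene, had 15.6 ± 1.90 CPM in normal cells and 0 counts in mECC, at least 529-fold lower, and Col1a2 was lower as well (38.6 ± 1.92 against 353 ± 36.6 CPM). Among 28 uterine identity and hormone response genes 21 were lower and 6 higher (camera adjusted p = 0.0191; adjusted p = 0.0966 with an estimated correlation). Ltf, the estrogen-induced lactoferrin gene, had 105299 counts in normal cells and 1 count in mECC (counting interval of the ratio 26100 to 5740000), and the homeobox gene Msx1 had 1592 and 1 (394 to 86800). Pgr, in contrast, was 4.32-fold higher in mECC.

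Among the genes with the largest rises in mECC, 3 had 0 counts in the normal libraries. They were the chemokine gene Cxcl15 (149 ± 11.5 CPM, at least 3670-fold higher), the angiotensinogen gene Agt (29.9 ± 2.51 CPM, at least 738-fold) and the aldehyde dehydrogenase gene Aldh3a1 (24.8 ± 1.3 CPM, at least 611-fold). The largest falls were in Prap1 (223544 counts in normal cells and 1 in mECC, counting interval 55300 to 12200000), Ltf, the surfactant protein gene Sftpd (508 ± 35.5 CPM to 0 counts, at least 17300-fold lower) and Crct1 (249 ± 19.1 CPM to 0 counts, at least 8450-fold lower). The highest edgeR adjusted p among these 7 genes was 1.68e-15.

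Mitosis genes were higher in mECC, 21 of 23 with 1 lower, led by Bub1b (3.76-fold) and Foxm1 (2.31-fold), with camera adjusted p = 5.59e-05 and adjusted p = 0.342 with an estimated correlation. Nucleolar and ribosome assembly genes were lower, 24 of 31 with 4 higher, led by the polyamine enzyme gene Odc1 (6.00-fold) and Utp20 (3.71-fold; camera adjusted p = 0.00106; adjusted p = 0.367 with an estimated correlation). Unfolded protein response genes were lower in 18 of 21 cases, with Ppp1r15a 4.91-fold and Dnajb9 4.60-fold lower (camera adjusted p = 6.05e-04; adjusted p = 0.0966 with an estimated correlation). Checkpoint ligands and immunosuppressive enzymes were lower in 13 of 19 cases and higher in 4, with Arg2 32.1-fold and the prostaglandin synthase gene Ptgs2 23.1-fold lower (camera adjusted p = 0.025; adjusted p = 0.342 with an estimated correlation). Oxidative phosphorylation genes were higher in 22 of 40 cases and lower in 10, with Ndufv2 2.05-fold and Ndufb10 1.99-fold higher (camera adjusted p = 0.0314; adjusted p = 0.408 with an estimated correlation). With library totals in place of TMM, the median of all genes moved from -0.02 to 0.22 on the log2 scale and the share of calls that were higher from 48.8% to 59.1%; with log2(TPM + 1) it was 59.8%. In HPmECC against normal cells the same change of scaling moved the median from 0.001 to 0.197. With library totals 8 nucleolar genes were higher and 16 lower in mECC, 33 oxidative phosphorylation genes were higher and 5 lower, and camera also called DNA replication (adjusted p = 0.0166) and glycolysis and hypoxia (adjusted p = 0.042). With a minimum of 10 CPM the camera calls of checkpoint ligands (adjusted p = 0.167), uterine identity (adjusted p = 0.10) and oxidative phosphorylation (adjusted p = 0.0662) were lost.

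The other lists were not called in mECC against normal cells. DNA replication genes were higher in 18 of 29 cases and lower in 10 (camera adjusted p = 0.10), and glycolysis and hypoxia genes were lower in 20 of 28 and higher in 7 (camera adjusted p = 0.0594). Cholesterol synthesis genes were lower in 13 of 22 and higher in 7 (camera adjusted p = 0.259), MYC network genes lower in 7 of 12 and higher in 4 (camera adjusted p = 0.376), and driver genes lower in 13 of 23 and higher in 10 (camera adjusted p = 0.52). Myeloid chemokines were lower in 15 of 22 and higher in 6 (camera adjusted p = 0.27), and lymphocyte chemokines lower in 3 of 6 and higher in 2 (camera adjusted p = 0.50). Interferon-stimulated genes were lower in 16 of 31 and higher in 10 (camera adjusted p = 0.50), MHC class I genes lower in 11 of 23 and higher in 10 (camera adjusted p = 0.52), and MHC class II genes lower in 4 of 5 and higher in 1 (camera adjusted p = 0.35). Mitochondrially encoded genes were lower in 3 of 13 and higher in 2 (camera adjusted p = 0.819), and adjusted over the list alone 0 were higher and 0 lower; for the other lists both counts were equal. With library totals 22 DNA replication genes were higher and 2 lower (median 0.51 in place of 0.27), 8 glycolysis and hypoxia genes higher and 16 lower, 12 interferon-stimulated genes higher and 13 lower, and 3 lymphocyte chemokines higher and 3 lower. On the same scaling 6 mitochondrially encoded genes were higher and 0 lower (median 0.25), 12 driver genes higher and 10 lower (median 0.10 in place of -0.14), 10 cholesterol synthesis genes higher and 9 lower, and 11 MHC class I genes higher and 10 lower. Median and mean differed in sign for MHC class I (0.02 and -1.25) and mitochondrially encoded genes (0.01 and -0.02). Of the sex-linked list only Xist, the RNA that silences an X chromosome, was tested. It held 16132 counts in the normal libraries, 10 in mECC and 4 in HPmECC.

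**Figure D4:**
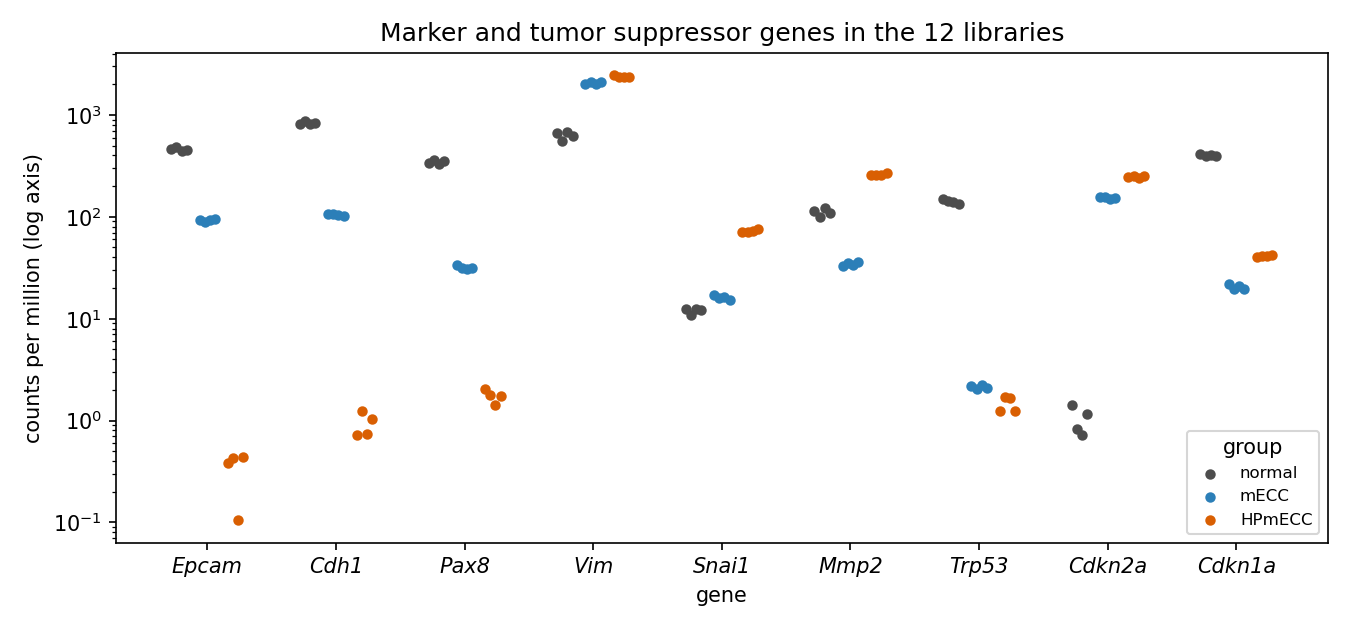
CPM on a log axis for 9 marker and tumor suppressor genes in the 12 libraries, colored by group. Epcam, Cdh1 and Pax8 step down from normal to mECC to HPmECC, and Trp53 lies at 2.14 CPM in mECC and 1.47 CPM in HPmECC against 141 CPM in normal cells.

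The comparison of HPmECC with normal cells asks the same of the other line. Of 28 epithelial genes 27 were lower and 1 higher, with a median log2 fold change of -8.74. Ap1m2 had 8326 counts in normal cells and 1 in HPmECC (counting interval of the ratio 1970 to 434000), and Epcam was 1270-fold lower. Keratin genes remained, with Krt8 at 124 CPM, Krt19 at 96.4 CPM and Krt7 at 30.8 CPM against 2563, 328 and 1968 CPM in normal cells. The camera call (adjusted p = 3.73e-09) was lost with an estimated correlation (adjusted p = 0.144). Trp53 was at 1.47 ± 0.26 CPM and Cdkn2a at 249 ± 5.31 CPM. Of 22 p53 targets 17 were lower and 5 higher, with Eda2r 181-fold and Pmaip1, a death-promoting gene, 33.2-fold lower, and this call held with an estimated correlation (camera adjusted p = 7.91e-04; adjusted p = 0.0365). In total, 6575 genes were higher and 6625 lower, 86.4% of those tested, and with a 2-fold minimum 2828 and 3517.

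Uterine identity genes were lower in 22 of 28 cases and higher in 5, and the call held with an estimated correlation (camera adjusted p = 0.00119; adjusted p = 0.0365). Sox17, a regulator of the uterine epithelium, had 361 ± 7.39 CPM in normal cells and 0 counts in HPmECC, at least 11800-fold lower. The other largest falls were in Acod1, the itaconate enzyme gene (424 ± 22.5 CPM to 0 counts, at least 13800-fold), Crct1 (at least 8090-fold) and the protease gene Tmprss4 (at least 6710-fold). The largest rises were in Tnn, a tenascin gene with 210 ± 9.90 CPM in HPmECC and 1 count in normal cells (counting interval 2800 to 615000), Sox2 (30.7 ± 2.31 CPM and 0 counts, at least 757-fold), Foxd1 (85.2 ± 2.40 CPM and 2 counts, counting interval 873 to 26100) and F13a1, a coagulation factor subunit gene (665 ± 61.1 CPM, 2540-fold). The highest edgeR adjusted p among these 8 genes was 9.02e-17.

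Mitosis genes were higher in 23 of 23 cases, with Bub1b 5.22-fold and Nusap1 3.11-fold higher (camera adjusted p = 1.70e-08; adjusted p = 0.249 with an estimated correlation), and DNA replication genes in 20 of 29 with 4 lower, led by Rfc3 (4.04-fold) and Rfc4 (2.53-fold; camera adjusted p = 0.00119; adjusted p = 0.482 with an estimated correlation). Nucleolar and ribosome assembly genes did not move as a set although Myc was higher than in normal cells: 12 of 31 were higher and 15 lower (camera adjusted p = 0.907). With library totals 17 were higher and 10 lower, and the median turned from -0.02 to 0.18. Mesenchymal genes were higher in 23 of 29 cases and lower in 6, with Postn 269-fold higher and Thy1 74.1-fold lower (camera adjusted p = 1.38e-04; adjusted p = 0.379 with an estimated correlation). Oxidative phosphorylation genes were higher in 31 of 40 cases and lower in 6, with Ndufv2 2.03-fold higher (camera adjusted p = 5.21e-04; adjusted p = 0.249 with an estimated correlation).

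Most markers of other cell types that the normal cultures held were lower in HPmECC too. Exceptions included the endothelial genes Flt1 (11.7 against 7.12 CPM) and Egfl7 (10.7 against 4.95 CPM), which were higher, and Acta2, which was lower but remained at 213 CPM. The mesothelial gene Bnc1 (41.1 against 36.8 CPM) was called higher (edgeR adjusted p = 0.03), but not with median-of-ratios factors (edgeR adjusted p = 0.0884) or without any of 4 single libraries (edgeR adjusted p from 0.0533 to 0.154). All 15 leukocyte genes were lower, with Lyz2 819-fold lower and Itgam at 1 count against 720 (counting interval 170 to 37600; camera adjusted p = 3.41e-04; adjusted p = 0.144 with an estimated correlation). Smooth muscle genes were lower in 11 of 12 cases and at least 2-fold higher in 1, with Tagln 862-fold and Myh11 43.9-fold lower (camera adjusted p = 0.00206; adjusted p = 0.36 with an estimated correlation). Mesothelial genes were lower in 6 of 7 cases, with 0 counts of Upk3b (at least 712-fold lower) and Upk1b (at least 551-fold; camera adjusted p = 0.0262; adjusted p = 0.379 with an estimated correlation). Endothelial genes were lower in 6 of 9 cases and higher in 2 (camera adjusted p = 0.17), with 0 counts of Cdh5 (at least 1300-fold lower) and Esam 185-fold lower. Checkpoint ligands and immunosuppressive enzymes were lower in 15 of 19 cases, with Arg2 64.0-fold and Ptgs2 23.7-fold lower (camera adjusted p = 0.0367; adjusted p = 0.364 with an estimated correlation). Unfolded protein response genes were lower in 13 of 21 cases and higher in 6, with Dnajb9 6.58-fold and Ppp1r15a 4.63-fold lower (camera adjusted p = 0.0435; adjusted p = 0.335 with an estimated correlation). That last camera call was lost without HPmECC replicate 4 (adjusted p = 0.0915), with a minimum of 10 CPM (adjusted p = 0.053) and with library totals (adjusted p = 0.176; 9 higher and 11 lower). The minimum of 10 CPM also ended the camera calls of checkpoint ligands (adjusted p = 0.205) and mesothelial genes (adjusted p = 0.053).

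The remaining lists were not called in HPmECC against normal cells. Glycolysis and hypoxia genes were higher in 14 of 28 cases and lower in 8 (camera adjusted p = 0.471), cholesterol synthesis genes higher in 13 of 22 and lower in 9 (camera adjusted p = 0.272), and MYC network genes higher in 5 of 12 and lower in 7 (camera adjusted p = 0.72). Driver genes were higher in 11 of 23 and lower in 12 (camera adjusted p = 0.926), myeloid chemokines higher in 8 of 22 and lower in 13 (camera adjusted p = 0.608), and interferon-stimulated genes higher in 9 of 31 and lower in 19 (camera adjusted p = 0.272). MHC class I genes were higher in 7 of 23 and lower in 15 (camera adjusted p = 0.17), and MHC class II genes higher in 3 of 5 and lower in 2 (camera adjusted p = 0.625). Lymphocyte chemokines were higher in 2 of 6 and lower in 3 (camera adjusted p = 0.682), and mitochondrially encoded genes higher in 1 of 13 and lower in 6 (camera adjusted p = 0.786). Adjusted over the list alone, 3 lymphocyte chemokines were higher and 3 lower, and 1 mitochondrially encoded gene was higher and 5 lower; for the other lists both counts were equal. With library totals 4 mitochondrially encoded genes were higher and 3 lower, and 11 driver genes higher and 8 lower. Median and mean differed in sign for glycolysis (0.26 and -0.22), where camera's direction was up, and for MHC class II (1.40 and -1.32).

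Both cancer lines differed from normal cells in many genes in the same direction. Against the shared normal libraries, 5428 genes were higher in both lines, 5727 lower in both and 815 opposite; with library totals in place of TMM 381 of the 815 remained so. Independent lists of these sizes would share 2769 higher and 2925 lower genes, and simulated unchanged groups against the same controls shared 0 (mean of 20 draws). No gene was changed in those draws, so their 0 shared calls do not measure how far shared controls add to the overlap. With the controls split, normal replicates 1 and 2 for mECC and 3 and 4 for HPmECC, 5065 of 14899 genes were higher in both, 5423 lower in both and 601 opposite. The log2 fold changes of both comparisons had a covariance of 5.85 across genes, against 0.014 in the simulations, and 5.88 with split controls. Their correlation was 0.887, and 0.895 with split controls. In the simulations, where only the shared controls link both comparisons, its mean was 0.536. The split controls were all libraries of the same normal group and may be technical repeats. The split therefore removes only the noise of shared libraries. Whatever sets the normal cells apart from both lines, such as their leukocyte and mesothelial transcripts, stays in both comparisons. The split values thus cannot tell how much of the overlap comes from the shared reference. Of the 5428 genes higher in both lines, 1919 were higher and 1798 lower in HPmECC than in mECC.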

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

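The tests of copy gain around Myc, of Myc transcript length, of the Y chromosome and of opposite directions under other scalings were chosen only after the result was seen.

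Myc was higher in HPmECC than in mECC by 2.165 on the log2 scale, while mECC lay below normal cells (-0.90) and HPmECC above them (1.26). A 2-fold gain of the wider region was argued against. The 21 protein-coding genes tested within 4 Mb had a median log2 fold change of 0.04 with an upper 95% bootstrap bound of 0.275, and 0 exceeded 1. The nearest of them, Fam84b, lies at -1166 kb from Myc, so a gain of Myc and its close surroundings was not tested. The noncoding neighbor Pvt1 was higher by 0.404 (edgeR adjusted p = 9.27e-04). Protein-coding genes of chromosome 15 with a mean of at least 10 CPM had a relative median of 0.29 between the lines. A smaller gain was therefore not argued against. The scaling of the libraries was argued against as well, because the lowest log2 fold change over 3 scalings was 2.12. A change of transcript length alone was argued against as the source of the rise, because TPM, which allows for length, gave a log2 fold change of 2.53. Shorter Myc transcripts in HPmECC remain possible. The mean log2 length implied by counts over TPM was -0.43 in HPmECC relative to mECC (SD 0.024, n = 4). All 4 HPmECC libraries lay below the other 8, and 0.32% of 9836 genes shortened as much. A candidate explanation is an introduced Myc carrying part of the transcript, or use of another isoform, and these data do not part them.

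In each comparison the real split of the 8 libraries was the only 1 of 35 splits to give as many called genes. The libraries of a group may be technical repeats, so this share cannot tell whether single cultures differ by chance. The real splits called 10182 genes for HPmECC against mECC, 12958 for mECC against normal and 12867 for HPmECC against normal, and the highest other split called 0 in each. The other splits mix libraries of both groups, whose difference then counts as spread, so their 0 calls are no estimate of false calls.

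Of 334 groups of 4 libraries examined over the genes followed here, 16 held a library far from the other 3 by Dixon's criterion; chance flags about 1 in 20 groups. In the normal group these were Ccl7 in replicate 3 (21.93 CPM), Acan in replicate 3 (0.7713 CPM), Itgam in replicate 3 (7.713 CPM), Cdt1 in replicate 2 (27.74 CPM), Cd74 in replicate 2 (3.013 CPM), Snai1 in replicate 2 (10.8 CPM), Cd14 in replicate 2 (165.0 CPM) and Col1a2 in replicate 2 (297.7 CPM). In mECC they were H2-DMb1 in replicate 4 (4.596 CPM), Igf2 in replicate 4 (27.41 CPM) and Col1a2 in replicate 2 (41.46 CPM). In HPmECC they were Mif (615.7 CPM), Car9 (8.251 CPM) and Slc2a1 (140.1 CPM) in replicate 4, Agt in replicate 1 (8.568 CPM) and Rfc3 in replicate 3 (56.63 CPM).

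Changes against normal cells ran in opposite directions in the cancer lines for 815 genes, of which 456 were higher and 359 lower in HPmECC, and 23 of the genes followed here were among them. Many of these directions depend on the scaling. With library totals in place of TMM, 659 genes called in mECC against normal and 461 called in HPmECC against normal changed sign, and 381 of the 815 remained opposite. With split controls 601 of 14899 genes were opposite. With library totals Mcm6 (0.11) and Mif (0.15) were higher than normal in mECC as well, and Dkc1 and Egfl7 were no longer called there. With median-of-ratios factors Bnc1, Chac1 and Uqcrc2 were no longer called in HPmECC against normal. The difference itself was tested by edgeR as the log2 fold change of HPmECC over mECC. It was positive for Myc (2.165), Ccl7 (1.572), Cspg4 (7.342), Hspb7 (5.164), Dkc1 (0.737), Mcm6 (0.778), Mif (0.979), Cd74 (3.258), H2-DMb1 (2.197), Mmp2 (2.914), Flt1 (2.96), Egfl7 (1.551), Bnc1 (1.331), Uqcrc2 (0.41), Trib3 (2.311) and Chac1 (1.842). It was negative for Cdh16 (-12.58) and Ppp2r2c (-10.763), whose fitted values rest on 0 and 1 counts in HPmECC, and for Cxcl5 (-1.147), H2-T23 (-1.978), Foxj1 (-5.412), Wnt4 (-4.055) and Peg3 (-5.352).

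The 4 Y-linked genes of the sex-linked list held 5 counts in mECC, 0 in HPmECC and 0 in normal cells.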

How the results depend on the processing

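The block of replicates 1 and 2 against 3 and 4 was chosen only after the result was seen, and every other alternative before the data were examined. Required to change by at least 2-fold, 1029 genes were higher and 1436 lower in HPmECC than in mECC, 2805 and 3485 in mECC than in normal cells, and 2828 and 3517 in HPmECC than in normal cells. Camera called 9, 13 and 12 lists in these comparisons; with an estimated correlation it called 2, 1 and 2, and fry, which does not compare a list with other genes, called 22, 23 and 21. The other gene counts stayed within 1.5 times the reported ones under every alternative run. Leaving out each library in turn gave 5013 to 5189 higher and 5101 to 5140 lower genes for HPmECC against mECC, 6373 to 6434 and 6662 to 6799 for mECC against normal, 6512 to 6561 and 6564 to 6682 for HPmECC against normal, and 9 to 10, 13 to 13 and 11 to 12 called lists. The Myc log2 fold change between the lines ran from 2.105 to 2.198 without single libraries and from 2.105 to 2.531 over all alternatives.

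With the replicate number as a block, 5111 genes were higher and 5210 lower in HPmECC than in mECC, 6405 and 6718 in mECC than in normal, and 6539 and 6607 in HPmECC than in normal; 9, 13 and 11 lists were called and the Myc log2 fold change was 2.162. The block ended the call of the unfolded protein response in HPmECC against normal (camera adjusted p = 0.0602). Residuals of libraries with the same number correlated from -0.027 to 0.08, and 6 of 12 matched their own number best, where chance gives 1 in 4. Mitochondrial shares were lower in replicates 1 and 2 than in 3 and 4 of normal cells (0.821% and 0.855% against up to 1.28%) and of mECC (down to 1.18% against 1.45% and 1.33%). With replicates 1 and 2 against 3 and 4 as a block, 5152 genes were higher and 5255 lower in HPmECC than in mECC, 6430 and 6744 in mECC than in normal, and 6560 and 6616 in HPmECC than in normal; 9, 13 and 12 lists were called, Myc was at 2.164 and all 253 gene results kept direction and side.

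Of 4782 values of 253 gene results under the alternatives, 4737 kept direction and side of the threshold, 23 lost the call, 14 gained it and 8 reversed. In HPmECC against normal, Ncl turned to 0.049 with library totals and to 0.122, 0.122 and 0.122 with TPM plus 1, TPM plus 0.1 and unfiltered TPM plus 1. In the same order, Npm1 turned to 0.146, 0.152, 0.152 and 0.152. The cause was not tested.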

Other observations

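The tests of the Y chromosome and of X reactivation, the lists of imprinted genes and of transcription factors of other lineages, and the genes named in this part were chosen only after the result was seen. Chromosome 14 was picked from these data because its shift stood out, so its tests were later choices too.

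Some transcription factors of other lineages were expressed in both cancer lines, at levels from 1.09 CPM (Prdm6 in mECC) upward. Foxd1, a kidney stroma factor, stood at 70.1 CPM in mECC and 85.2 CPM in HPmECC against 0.0339 CPM in normal cells, and Sox2, a stem cell factor, at 13.4 and 30.7 CPM against 0 counts. All 12 such factors were called higher in both lines, but they were listed because of their values, so the count is no evidence of a trend. Imprinted genes divided: of 22 tested, 8 were higher and 12 lower in mECC than in normal cells, and 9 higher and 12 lower in HPmECC. H19 stood at 59.2 and 59.1 CPM in mECC and HPmECC against 1.64 CPM in normal cells, Igf2 at 23.6 and 1.85 CPM against 0.329 CPM, and Peg3 at 35.3 and 0.858 CPM against 13.8 CPM.

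Genes on chromosome 14 were lower in both cancer lines than in normal cells. The chromosome values in this part cover only protein-coding genes with a mean of at least 10 CPM over all libraries. Relative to the other autosomes the median log2 fold change of 317 such genes was -0.95 in mECC and -0.81 in HPmECC. Of them, 83.6% and 80.8% were called lower, against 44.4% and 43.3% on the other autosomes. GC content and transcript length were argued against as the cause, since 98.9% and 101.7% of the relative median were kept after adjustment. A few local gene clusters were argued against only within the bins of 10 Mb that held at least 20 of these genes. Of those bins, 6 of 6 in mECC and 6 of 6 in HPmECC lay below the autosome median. Stretches with fewer genes were not examined. Other cell types in the normal cultures were argued against because the upper quartile was shifted as well, with upper 95% bootstrap bounds of -0.858 and -0.72. A hypothesis is that both lines may have lost a copy of chromosome 14; DNA was not analysed here, so this stays open.

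Xist held 216 CPM in normal cells, 0.0986 CPM in mECC and 0.0409 CPM in HPmECC. Male cells were argued against, because the higher of the lines' total counts of 4 Y-linked genes was 5; loss of a Y chromosome in culture was not tested. Reactivation of the whole silent X was argued against: the X median relative to autosomes had upper 95% bootstrap bounds of 0.229 in mECC and 0.254 in HPmECC. Loss of the silent X chromosome, or silencing of Xist alone, may remain and was not tested.

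Other chromosomes also differed from the autosome median. Against normal cells the relative median was 0.63 and 0.60 for chromosome 5 and 0.47 and 0.48 for chromosome 17 in mECC and HPmECC, 0.43 and 0.24 for chromosome 2, -0.53 and -0.21 for chromosome 12, and 0.20 and 0.43 for chromosome 15, which carries Myc. Between the lines it was 0.32 for chromosome 12, 0.29 for chromosome 15 and -0.23 for chromosome 8.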
